A study of Homo sapiens with 4 samples.

How the data were processed

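Total RNA from the Hodgkin lymphoma cell line KM-H2 was measured on 4 Affymetrix arrays, 2 from PTPN1 knockdown cells and 2 from non-silencing controls. Per the labels' protocols, RNA was extracted on columns and biotinylated cRNA was made with 2 cycles of amplification, a step that can favour the 3' ends of transcripts and add differences between preparations. The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes, a method that corrects background, normalizes arrays by quantiles and summarises probes into probe sets. The software and version behind that step are not given in the sources used here. RMA gives every array nearly the same distribution, so a change in total RNA per cell cannot be seen, and it compresses differences among dim probe sets. Arrays were assigned to their groups by their titles, and array numbers are the replicate numbers in those titles.

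Gene names came from a table pairing probe sets with the platform's annotation, with symbols looked up by gene identifier in a RefSeq gene table of assembly GRCh38.p14. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. For 54 of the probe sets with 1 symbol the gene was not found in the RefSeq table and the platform's symbol was kept, and 0 symbols were renamed. Probe sets with several genes or none were not used for named genes. Each gene was represented by its probe set with the highest mean over the 4 arrays, which left 19775 genes, 10523 of them with several probe sets. Genes outside that table are not analysed here. The order of neighbouring genes was also taken from GRCh38.p14, since the values carry no positions.

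The deposited values were used without further normalization. Knockdown was compared with non-silencing in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes, with 0.05 as the threshold. Tests were two-sided. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 35 lists, and again with a correlation estimated per list. The estimated form rests its p-values on the few arrays and not on the many genes. With 4 arrays hardly any list could pass it. Percentiles of list medians came from 10000 random lists matched on mean expression in 20 bins. Differences between the array numbers were tested in a fit with terms for both group and number. Intervals of list medians are 95% bootstrap intervals over genes from 2000 resamples, and describe genes, not arrays.

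The gene lists, the tests and the rule for named genes were set before the data were examined. The lists hold 831 genes, of which 756 were measured. The rule for named genes took PTPN1, then the 12 genes with the highest and the 12 with the lowest difference among genes past the threshold whose higher group mean reached the median of all probe sets (5.11), with XIST and Y-linked genes left out, then up to 4 passing members of each list, and any member of the lists of JAK-STAT targets, interleukin-4 targets and JAK-STAT components. No gene passed, so the ranking was applied without the threshold to genes with both knockdown arrays on the same side of both non-silencing arrays, and members of other lists were named after their values were seen.

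The method was tested on simulated data with 19775 genes, 50 changed genes of each size and the differences between array numbers kept in the noise. It recovered 0% of genes changed by 1 on the log2 scale, 80% of those changed by 2 and 98% of those changed by 3, with 0 unchanged genes called. Without the differences between numbers in the noise it recovered 84% of genes changed by 1, with 13 unchanged genes called. With no list shifted, 0 of 35 lists were called, and the JAK-STAT target list was called when shifted by 0.3. Apart from the differences between numbers, the noise was drawn for each gene separately, in a single draw. The shift also exceeds the measured median of 0.19. This cannot gauge false list calls where genes vary together.

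Alternatives were quantile normalization, centring of arrays, other choices of probe set, filters on dim genes, other variance models, a test against a fold of 1.2, a replicate block, an estimated correlation, a rank-based camera and leaving out each array. Further settings chosen after seeing the data were differences within an array number, the replicate block together with an estimated correlation, counts of 2-fold differences without a test, and lists without members in stretches of neighbouring genes. Runs of neighbouring genes were sought with medians over windows of 25 genes, set against 100 shuffled gene orders. Several tests of explanations were replaced after their results were seen. A floor under dim genes was first tested on genes whose mean over all arrays was at or above the median signal (77.6% higher), which keeps genes that are dim in 1 group only. Other cell types were first judged by list medians (highest upper 95% bound 0.14), which bright markers can hold near 0. Effects of the array numbers on neighbouring genes were first sought by regression, which kept 67.5% of the extreme windows, short of the share set for it, and 5 of 5 run medians beyond random genes, 4 of them by more than their bootstrap interval. Within an array number 5 of 5 runs did so in at least 1 number and 2 in both. These tests were dropped, because each group holds an array of each number, so that such effects cancel, and because the runs were chosen from the same differences. A test of the JAK-STAT list without members inside runs (percentile 100) was dropped too, since it removes 1 of 29 members. A single array was first judged by the sign of each run, which 5 of 5 kept, but a sign can be kept by chance. The next rule would have made a single array the source of the run from ZNF438 to PARD3. It was changed because that run's median also lay beyond random genes within both numbers. That ground is weak, as between the arrays numbered 1 its bootstrap interval reached 0.00070. Leaving out an array also lets the numbers into the difference.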

Results

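RNA from KM-H2, a cell line derived from Hodgkin lymphoma, was profiled on 4 Affymetrix expression arrays. A pair of arrays came from cells in which PTPN1 was knocked down with small interfering RNA, and the other pair from cells given a non-silencing control. Each array gave a log2 expression value for 54675 probe sets, from which 19775 genes were compared. Array medians were 5.12 and 5.12 for the non-silencing arrays and 5.11 and 5.10 for the knockdown arrays. The number of arrays limits the precision, with 2 in each group. The series describes the arrays of a group as technical replicates, so that SDs, SEs and p-values measure the technical spread between arrays and not the spread between cultures.

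The comparison asked how gene expression in these lymphoma cells differs when PTPN1, a tyrosine phosphatase known to act on JAK kinases, is reduced. PTPN1 itself was lower in both knockdown arrays. The brightest of its 4 probe sets read 8.28 ± 0.17 (SD, n = 2) in the non-silencing arrays and 7.18 ± 0.26 (SD, n = 2) in the knockdown arrays, a log2 difference of -1.10 (SE 0.18) that left 46.8% of the signal. The difference was -1.16 between the arrays numbered 1 and -1.03 between the arrays numbered 2, but its limma adjusted p of 0.769 did not pass. With the replicate number as a block the limma adjusted p was 0.0251, but the labels tie a number to no shared batch. The remaining PTPN1 probe sets differed by 0.01, -0.07 and -0.03 on the log2 scale. All 3 lay below 5.11, the median of all values, in both groups.

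FDCSP, DLK1, IL12B and SERPINA6 had the largest positive differences, with more transcript in both knockdown arrays, although no single gene passed the test. FDCSP, a small protein secreted by follicular dendritic cells, read 5.22 ± 0.52 (SD, n = 2) in the non-silencing arrays and 10.33 ± 0.70 in the knockdown arrays, a log2 difference of 5.11 (SE 0.41). DLK1, a Delta-like ligand of the Notch family, read 6.59 ± 1.19 against 11.51 ± 0.14, a difference of 4.92 (SE 0.55) that was 2.54 with the mean of all its probe sets. IL12B, a cytokine subunit, read 3.23 ± 0.23 against 7.07 ± 0.92, a difference of 3.84 (SE 0.44). SERPINA6, the corticosteroid-binding globulin of plasma, differed by 3.25 (SE 0.40). Within each array number these differences were 5.24 and 4.99 for FDCSP, 3.98 and 5.86 for DLK1, 4.65 and 3.03 for IL12B, and 3.47 and 3.02 for SERPINA6.

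Smaller positive differences were measured for the long non-coding RNA LINC01933 (2.54), the nuclear protein gene AFF3 (2.54), NOL4 (2.50), the Hippo pathway coactivator YAP1 (2.45) and SPP1, which encodes osteopontin (2.43). The mesenchymal homeobox gene PRRX1 (2.38), the lipid transporter gene ABCA8 (2.37) and TTC7B (2.32) completed the 12 highest. LINC01933 read 5.03 in knockdown array 1 and 7.51 in knockdown array 2, so that its group mean averages unequal values. Without 1 array LINC01933 ranged from 1.30 to 3.77 and PRRX1 from 1.5 to 3.27. AFF3 and TTC7B had the tightest values, with SEs of 0.17 and 0.13, but with the mean of all its probe sets AFF3 differed by 0.40. By the same mean LINC01933 differed by 1.31, SPP1 by 1.29, ABCA8 by 0.87, YAP1 by 1.65 and PRRX1 by 1.71. In the non-silencing arrays IL12B, LINC01933 (3.73), AFF3 (3.68), NOL4 (4.03), YAP1 (3.85) and TTC7B (3.12) lay below 4.10, the lower quartile of these arrays, so that the size and order of their differences are uncertain.

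Among genes with less transcript in the knockdown arrays, TMEM100, a membrane protein of endothelial and lung cells, differed by -1.92 (SE 0.39) and KLHL13, an adaptor of a cullin ubiquitin ligase, by -1.67 (SE 0.18). The gastrokine genes GKN1 and GKN2, which encode secreted proteins of the stomach lining, differed by -1.35 (SE 0.14) and -1.09 (SE 0.27). The immunoglobulin genes IGHM and IGLC1 both differed by -1.30, with SEs of 0.71 and 0.21 (-0.53 and -0.26 with the mean of all their probe sets), and belong to families of similar sequence that a probe set may not separate. For IGHM the difference was -2.32 between the arrays numbered 1 and -0.28 between those numbered 2, and without 1 array it ranged from -2.41 to -0.19. The centrosomal gene KIZ (-1.22), SELENOP, which encodes the selenium carrier of plasma (-1.21), CTXN3 (-1.18), the ribonuclease gene RNASE6 (-1.08) and the nuclear receptor gene NR5A2 (-1.08) followed, and PTPN1 ranked ninth of the 12 lowest. Without 1 array CTXN3 ranged from -1.70 to -0.65, RNASE6 from -1.62 to -0.55 and NR5A2 from -1.65 to -0.50, and with the mean of all probe sets KIZ was -0.61, SELENOP -0.76 and NR5A2 -0.49.

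**Figure D1:**
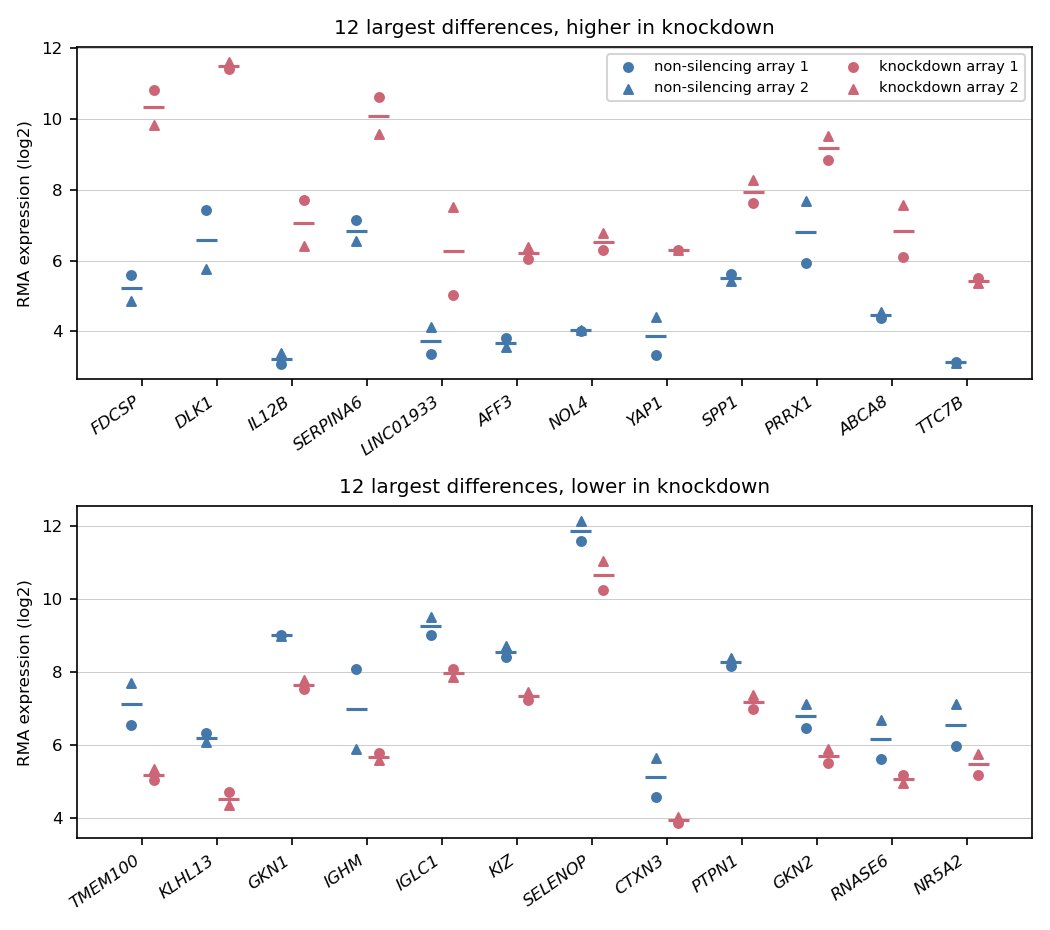
Log2 expression (vertical axis) of the 12 genes with the highest and the 12 with the lowest difference between knockdown and non-silencing arrays (horizontal axis), with 1 point per array, circles for arrays numbered 1, triangles for arrays numbered 2 and a bar at each group mean. The groups are apart for each gene shown, from 5.22 against 10.33 for FDCSP to 6.55 against 5.48 for NR5A2, and for IGHM the non-silencing arrays read 8.10 and 5.89.

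In limma, 0 of the 19775 genes had an adjusted p under 0.05, and the lowest adjusted p, 0.127, was shared by 11 genes. This fit keeps the differences between array numbers in the spread. In the simulation it recovered 0% of genes changed by 1, so 0 calls do not show that no gene differed. At an unadjusted p under 0.05 there were 509 genes, 290 higher and 219 lower in knockdown, where chance alone gives 989 if the arrays are interchangeable. An unmoderated linear model also called 0 genes. Because none passed, the 24 genes above were ranked without the threshold, among genes whose arrays do not overlap between the groups, a choice made after the values were seen. In all, 85 genes were at least 2-fold higher and 32 at least 2-fold lower, of which 79 and 17 had the groups apart, and 52 and 10 were at least 2-fold apart within both array numbers. At 4-fold the counts were 23 higher and 0 lower. Groups were apart for 27.4% of all genes, against 33.3% by chance if the arrays are interchangeable. Same-numbered arrays were more alike than arrays of a group, which can lower both counts. The shortfalls therefore do not show a lack of difference between the groups. With the replicate block 2046 genes had an unadjusted limma p under 0.05. DLK1 differed by 5.76 without non-silencing array 1 and by 4.08 without non-silencing array 2. Its spread lay in the non-silencing arrays (SD 1.19, against 0.14 in the knockdown arrays). A fit without either of them loses that spread, so it adds no support for DLK1.

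Arrays with the same number resembled each other more than arrays of the same group. Across the 19775 genes, which are not independent replicates, Pearson's r was 0.994 between the arrays numbered 1 and 0.995 between those numbered 2, against 0.991 between the non-silencing arrays and 0.989 between the knockdown arrays. The difference between 3' and 5' beta-actin control probe sets, a measure of RNA integrity and amplification, was 1.31 and 1.33 in the arrays numbered 1 and 0.972 and 0.969 in those numbered 2. The 18S ribosomal RNA control probe sets averaged 11.9 and 11.7 in the non-silencing arrays and 12.4 and 12.2 in the knockdown arrays. Smallest of the p-values that an exact permutation of 2 against 2 arrays can give is 0.333, so no single value can pass such a test.

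Genes known as direct targets of JAK-STAT signalling were higher as a list in the knockdown arrays. Of 29 measured members 22 lay above 0, and the median log2 difference was 0.19 (camera adjusted p = 1.8e-04). With an estimated correlation the call was lost (adjusted p = 0.736). BCL6, a transcriptional repressor of germinal centre B cells, read 8.14 ± 0.12 (SD, n = 2) in the non-silencing arrays and 8.85 ± 0.16 in the knockdown arrays, a difference of 0.71 that was 0.74 and 0.68 within the array numbers. Other positive differences were 0.66 for the cell cycle inhibitor CDKN1A, 0.63 for the interleukin receptor gene IL2RA, 0.58 for the kinase gene PIM2 and 0.55 for the transcription factor gene IRF1. MYC differed by 0.38, the survival gene MCL1 by 0.27 and the adhesion molecule gene ICAM1 by 0.43. Among the feedback inhibitors of the pathway, SOCS2 differed by 0.29 and SOCS1 by 0.13, while CISH and SOCS3 lay at -0.01 and -0.07, but with the mean of all its probe sets SOCS3 was 0.51. CCND1, which encodes cyclin D, went the other way by -1.05 with an SE of 0.57. Leaving out 1 array moved CDKN1A from 0.41 to 0.91, IL2RA from 0.19 to 1.08, PIM2 from -0.23 to 1.40, IRF1 from 0.18 to 0.91, MYC from -0.23 to 0.99, MCL1 from 0.083 to 0.45, ICAM1 from 0.21 to 0.65 and CCND1 from -1.94 to -0.17. No member passed, whether adjusted over all genes or adjusted over the list alone.

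The list's median was 0.35 between the arrays numbered 1 and 0.07 between those numbered 2. Without knockdown array 1 it was 0.013, and the call was lost (adjusted p = 0.292), with MYC and PIM2 each at -0.23. The list also differed between the array numbers, by a median of -0.19 for number 2 minus number 1 (camera adjusted p = 0.0382), as did the beta-actin ratio.

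**Figure D2:**
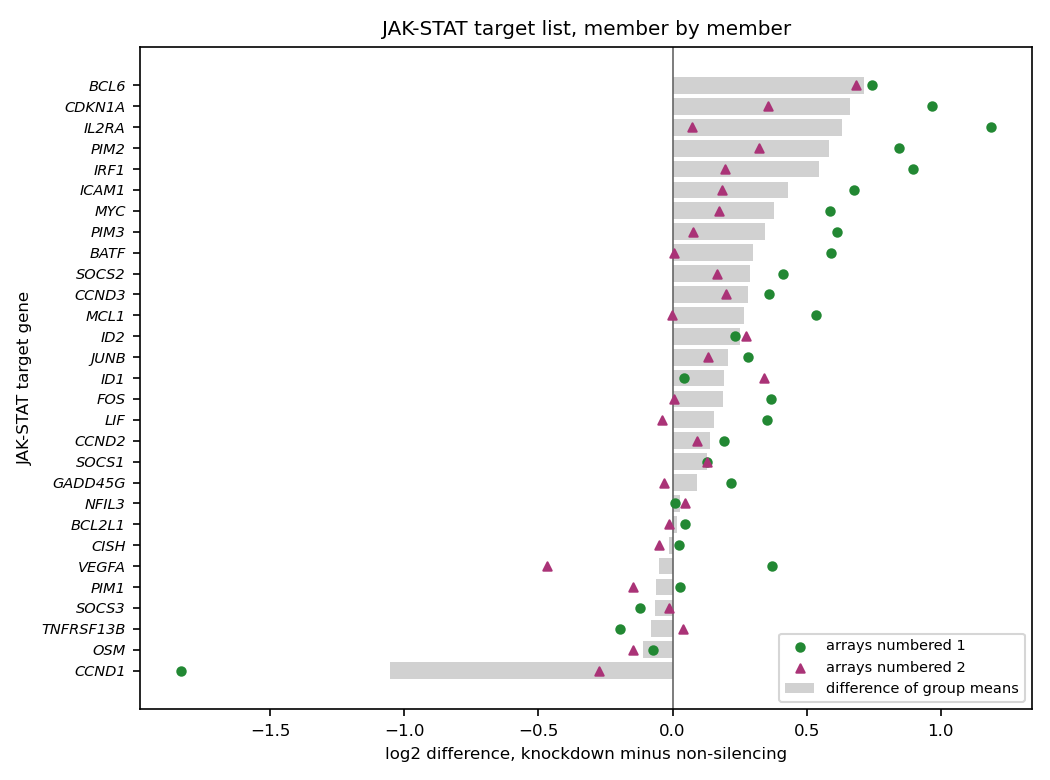
Log2 difference, knockdown minus non-silencing (horizontal axis), of each measured JAK-STAT target gene (vertical axis), with bars from 0 for the difference of group means and points for the arrays numbered 1 and numbered 2. Of 29 genes 22 have bars above 0, BCL6 being the highest at 0.71 and CCND1 the lowest at -1.05, and for IL2RA the points lie apart at 1.19 and 0.07.

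Neither the pathway's own components nor the targets of interleukin-4 signalling shifted as lists. The components had a median difference of 0.01 over 27 genes (adjusted p = 0.257, and 0.0155 without non-silencing array 2). Within them the transcription factor genes STAT4 and STAT3 stood highest, at 1.12 (SE 0.24) and 0.85 (SE 0.39), while the kinase genes JAK1 and JAK2 differed by -0.04 and 0.10, values that changed sign with the array left out. STAT3 read 9.66 in knockdown array 1 and 8.47 in knockdown array 2, against 8.22 ± 0.08 (SD, n = 2) in the non-silencing arrays, so that its difference ranged from 0.26 to 1.44 without 1 array, whereas STAT4 read 5.72 ± 0.02 against 4.60 ± 0.47. The interleukin-4 targets, activated through STAT6, had a median of 0.01 over 25 genes (adjusted p = 0.793). Among these the chemokine gene CCL17 differed by 0.97 (SE 0.23) and the transcription factor gene GATA3 by -0.44 (SE 0.12). No member of either list passed, adjusted over all genes or adjusted over the list alone.

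Antigen presentation genes of MHC class I were the list with the lowest p. All 15 measured members lay above 0, with a median difference of 0.22 (camera adjusted p = 3.8e-06) that was 0.23 and 0.19 within the array numbers. The call was lost with an estimated correlation (adjusted p = 0.736), and it held without each of the 4 arrays in turn. The peptide transporter genes TAP1 and TAP2 differed by 0.58 and 0.53, the immunoproteasome gene PSMB9 by 0.35 and HLA-B by 0.20, these and the members named from here on being chosen after their values were seen. Of the 15 members 2 lie in a stretch of 23 neighbouring genes, from ABCF1 to MICA-AS1, that was higher as a whole, and its 21 other genes had a median of 0.21. The median of the stretch was 0.20, and from 0.055 to 0.19 without 1 array. Outside that stretch the list's median was 0.25.

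Targets of NF-kB and genes of inflammation had a median difference of 0.12 over 32 members, 25 of them above 0 (camera adjusted p = 0.0013). The adjusted p = 0.736 with an estimated correlation and 0.0592 without knockdown array 1. The lymphotoxin gene LTA differed by 0.91 (SE 0.30), the cytokine subunit gene EBI3 by 0.71 (SE 0.23), TNF by 0.76 (SE 0.50) and the NF-kB inhibitor gene TNFAIP3 by 0.61 (SE 0.26). IL6 read 9.11 in knockdown array 1 and 6.97 in knockdown array 2, against 6.68 ± 0.04 (SD, n = 2) in the non-silencing arrays. Without 1 array LTA ranged from 0.57 to 1.26, EBI3 from 0.44 to 0.98, TNF from 0.20 to 1.32, TNFAIP3 from 0.34 to 0.89 and IL6 from 0.29 to 2.43. In the wider list of cytokines and chemokines, with a median of 0.03 over 35 genes (adjusted p = 0.257, 0.0025 without knockdown array 2, and 0.00446 with a median of 0.12 among genes at or above the median signal), IL12B was the only member past the threshold when adjusted over the list alone (limma adjusted p = 0.0106). IL21 there read 7.61 and 5.06 in the knockdown arrays against 4.72 ± 0.12 (SD, n = 2) in the non-silencing arrays.

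Interferon genes gave a mixed picture. The general interferon-stimulated list had a median of 0.05 over 43 members, 29 of them above 0 (camera adjusted p = 0.196). It passed without non-silencing array 2 (adjusted p = 0.00891) and without knockdown array 1 (adjusted p = 0.034). The list of interferon-gamma-type genes was called higher, with a median of 0.21 over 27 members (camera adjusted p = 0.0319, and adjusted p = 0.736 with an estimated correlation). Its median was 0.34 between the arrays numbered 1 and 0.04 between those numbered 2. Only leaving out non-silencing array 2 kept the call (median 0.22). The median was -0.0048 without non-silencing array 1, 0.078 without knockdown array 1 and 0.27 without knockdown array 2, where the shift itself remained. TAP1, TAP2 and IRF1 are members with positive differences, while the chemokine genes CXCL11 and CXCL10 differed by -1.23 (SE 0.60) and -0.86 (SE 0.52), and CIITA, the regulator of MHC class II genes, by -0.48 (SE 0.26). These ranged from -2.05 to -0.41, -1.60 to -0.12 and -0.74 to -0.22 without 1 array, and CIITA was -0.17 with the mean of all its probe sets.

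Early-response and stress genes were also higher as lists. Immediate-early and MAP kinase feedback genes had a median of 0.18 over 26 members (camera adjusted p = 1.6e-04, and 0.736 with an estimated correlation). Among them DUSP4 stood at 0.76 (SE 0.39, from 0.29 to 1.23 without 1 array), IER3 at 0.51 (SE 0.26, from 0.14 to 0.89), EGR1 at 0.34 (0.14 with the mean of all its probe sets) and JUN at 0.33. Genes of the integrated stress response had a median of 0.15 over 25 members (adjusted p = 0.00588, and 0.736 with an estimated correlation), among them the tRNA ligase gene GARS1 at 0.34 and the transcription factor gene ATF4 at 0.38, which was 0.84 and -0.08 within the array numbers. Heat shock genes had a median of 0.12 over 16 members (adjusted p = 0.00551, and 0.736 with that correlation), with the chaperone genes DNAJB1 at 0.40, DNAJA1 at 0.33 and HSPH1 at 0.30. Genes of the unfolded protein response had a median of 0.12 over 22 members (adjusted p = 0.0409, and 0.736 with that correlation), with HSP90B1 at 0.34 and DNAJB11 at 0.33. Targets of p53 had a median of 0.10 over 21 members (adjusted p = 0.0123, and 0.736 with that correlation), led by GDF15 at 0.80 (0.11 with the mean of all its probe sets) and CDKN1A at 0.66, with MDM2 at 0.27. With it all 5 calls were lost. Without 1 array GARS1 ranged from 0.22 to 0.46, ATF4 from 0.098 to 0.66, DNAJB1 from 0.10 to 0.70, HSP90B1 from 0.19 to 0.49, DNAJB11 from 0.20 to 0.46, GDF15 from 0.52 to 1.07 and MDM2 from 0.12 to 0.43.

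Without knockdown array 1 the medians fell to 0.06 for the immediate-early list (adjusted p = 0.162), -0.02 for the integrated stress response (0.923), 0.03 for heat shock (0.426) and 0.0020 for the unfolded protein response (0.603). Without non-silencing array 2 they were 0.10 for heat shock (0.0625) and -0.05 for the unfolded protein response (0.953). The p53 targets lost their call without non-silencing array 1 (adjusted p = 0.427) and without knockdown array 2 (0.118). The immediate-early and unfolded protein response lists also differed between the array numbers, by medians of -0.16 and -0.21 for number 2 minus number 1 (camera adjusted p = 0.0356 and 0.0218). Leaving out 1 array lets such differences into the medians above. Within numbers 1 and 2 the medians were 0.08 and 0.15 for the unfolded protein response and 0.16 and 0.10 for heat shock. For the immediate-early list they were 0.24 and 0.11, for the integrated stress response 0.23 and 0.06, and for p53 targets 0.18 and 0.05.

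Histone genes were the single list called lower, with a median difference of -0.29 over 16 members, 12 of them below 0 (camera adjusted p = 0.041, and adjusted p = 0.736 with an estimated correlation). The linker histone gene H1-2 read 10.98 ± 0.06 (SD, n = 2) in the non-silencing arrays and 10.35 ± 0.14 in the knockdown arrays, a difference of -0.63. The core histone genes H2BC5, H2AC6 and H2BC12 differed by -0.59 (SE 0.49), -0.57 (SE 0.36) and -0.44 (SE 0.40), and without knockdown array 1 by -0.013, -0.13 and -0.0078. The list differed between the array numbers too, by 0.25 for number 2 minus number 1 (camera adjusted p = 0.00362). Its median shrank to -0.055 without knockdown array 1 and to -0.052 without non-silencing array 2. Without non-silencing array 1 the median was -0.51, and without knockdown array 2 it was -0.50. Leaving out 1 array lets the difference between numbers into these values and those of the core histone genes. Between same-numbered arrays the list was lower in both pairs, with medians of -0.28 for number 1 and -0.40 for number 2. With the replicate block its camera adjusted p was 4.3e-04.

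Of the 35 lists, 9 were called higher and 1 lower, and with an estimated correlation 0 were called (lowest adjusted p = 0.736). Between the array numbers, where no knockdown is compared, camera at its preset correlation also called 9 of the 35 lists. Lowest in p there was ribosome biogenesis, with a median of -0.34 for number 2 minus number 1 (camera adjusted p = 1.5e-04). The count of lists called thus does not set the knockdown apart from differences between technical replicates. Genes of proliferation and of DNA replication had medians of -0.02 and -0.07 (adjusted p = 0.545 and 0.279), and ribosomal proteins and oxidative phosphorylation medians of -0.03 and -0.05 (adjusted p = 0.279 and 0.196). Cholesterol synthesis had a median of -0.04 (adjusted p = 0.545), which was -0.27 without non-silencing array 1 and 0.24 without non-silencing array 2. This list differed between the array numbers by 0.36 for number 2 minus number 1 (camera adjusted p = 2.7e-04). Such a difference enters the comparison when 1 array is left out, so these opposite medians show no effect of the knockdown. Without non-silencing array 2 the medians were -0.14 for DNA replication and -0.16 for oxidative phosphorylation, the latter -0.14 without knockdown array 1. Oxidative phosphorylation also differed between the array numbers, by -0.14 for number 2 minus number 1 (camera adjusted p = 0.0241). MHC class II genes had a median of 0.0035 (adjusted p = 0.504), and genes of B cell identity one of -0.06 (adjusted p = 0.513). Markers of other cell types, namely T cells, myeloid cells, stromal and epithelial cells and erythroid cells, had medians of 0.00021, -0.03, -0.01 and -0.10 (adjusted p = 0.513, 0.793, 0.513 and 0.279). The median and the test differed in sign for T cell and myeloid markers, and for the lists of fatty acid synthesis and cell adhesion.

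**Figure D3:**
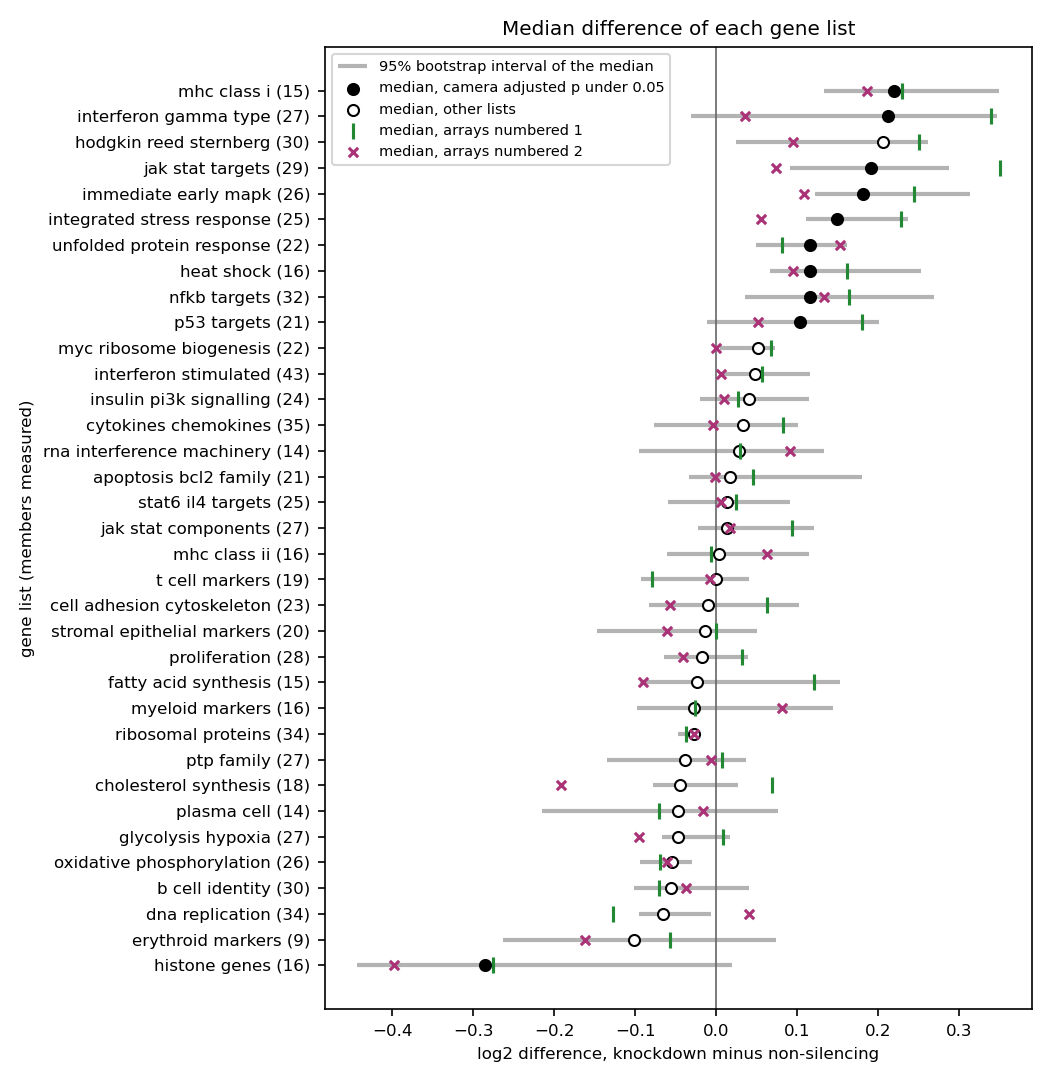
Median log2 difference, knockdown minus non-silencing (horizontal axis), of each of 35 gene lists (vertical axis, with the number of members measured), with bars for the 95% bootstrap interval over genes, filled circles for lists with camera adjusted p under 0.05, and ticks and crosses for the medians within arrays numbered 1 and numbered 2. MHC class I lies highest at 0.22 and histone genes lowest at -0.29, and the JAK-STAT targets lie at 0.35 and 0.07 within the array numbers.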

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

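Outside the comparison of named genes, 13 probe sets with no gene in the probe table were at least 2-fold higher in knockdown with the groups apart, and 1 was at least 2-fold lower. The 18S ribosomal RNA control probe sets, which measure no messenger RNA, were higher in knockdown by 0.55 on the log2 scale, and by 0.55 within each array number.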

How the results depend on the processing

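Differences within an array number, and the block together with an estimated correlation, were chosen after seeing the data. With 0 genes called, quantile normalization, centring, other probe set choices, filters on dim genes, robust and unmoderated fits and a test against a fold of 1.2 also called 0. An intensity trend called 1 gene, TTC7B, also past 2-fold (adjusted p = 0.0453), and leaving out an array called 0 to 1, also at 2-fold. The cause was not tested. Left-out fits assume that the lone array varies like the other group. Dim genes limit what can be seen, since 3 of 4 PTPN1 probe sets lie below the median signal.

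With the replicate block, 72 genes were called, 54 higher and 18 lower, and 60 of them at least 2-fold. They include 18 of the 24 ranked genes, PTPN1 among these (-1.10, adjusted p = 0.0251). Deviations of same-numbered arrays correlated at 0.648. In the limma fit with terms for group and number, 1948 genes differed between the numbers (adjusted p under 0.05). At least 2-fold, with or without passing, 250 genes differed. The arrays thus differ by number, but the labels tie a number to no shared batch, and 2 pairs do not settle what same-numbered arrays share. The block takes the differences between numbers out of the spread, and in the simulation it recovered 94% of genes changed by 1, with 17 unchanged genes called. Of the lists, the block ended the interferon-gamma-type call (adjusted p = 0.193) and added the list of Hodgkin cell genes (adjusted p = 0.0202). It kept the JAK-STAT target call (camera adjusted p = 8.0e-05).

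The number of lists called, 10 in the main setting, was 0 with an estimated correlation, 0 with that and the block, and 4 to 14 without 1 array. The JAK-STAT target median stayed 0.19 with adjusted p = 0.736 and 0.77 under those settings, and ranged from 0.013 to 0.31 without 1 array. The interferon-stimulated median ranged from -0.11 to 0.082, passing without non-silencing array 2 (0.064, adjusted p = 0.00891) and without knockdown array 1 (0.082, adjusted p = 0.034). The histone call was lost with quantile normalization (adjusted p = 0.0533) and a rank-based camera (0.100), which also ended the interferon-gamma-type call (0.100). The unfolded protein response missed with quantile normalization (0.0576), the mean of all probe sets (0.0805) and genes at or above the median (0.0567) or at or above 6 (0.0609). These filters added cytokines and chemokines (0.00446 and 0.0245), and the cut at 6 also Hodgkin cell genes (0.0492) and, as lower, oxidative phosphorylation (0.0373).

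Some differences shrank and a few reversed. With the mean of all probe sets AFF3 was 0.40, DLK1 2.54, LINC01933 1.31, SPP1 1.29, ABCA8 0.87, IGLC1 -0.26, IGHM -0.53, KIZ -0.61, SELENOP -0.76, NR5A2 -0.49, GDF15 0.11, EGR1 0.14, CIITA -0.17, STAT3 0.53, SOCS1 0.043 and PTPN1 -0.30. CISH was 0.0049 after centring and 0.025 between the arrays numbered 1. With that mean CISH was 0.034, SOCS3 0.51 and JAK1 0.054. Between the arrays numbered 2, MCL1 was -0.0021, ATF4 -0.082 and JAK1 0.053. Without 1 array CISH ranged from -0.22 to 0.19, MYC from -0.23 to 0.99, PIM2 from -0.23 to 1.40, JAK1 from -0.21 to 0.13 and JAK2 from -0.24 to 0.43. The cause was not tested.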

Other observations

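Genes characteristic of Hodgkin and Reed-Sternberg cells had a median log2 difference of 0.21 over 30 members, 20 of them above 0, which missed the threshold (camera adjusted p = 0.0785). The list passed without knockdown array 2 (adjusted p = 8.7e-04) and without non-silencing array 2 (adjusted p = 0.0444), but missed without non-silencing array 1 (adjusted p = 0.14) and without knockdown array 1, where its median was 0.024 (adjusted p = 0.588). CCL17, a chemokine that draws T cells, differed by 0.97 and the receptor gene CD40 by 0.39 (from 0.12 to 0.67 without 1 array), whereas GATA3 differed by -0.44. Genes of insulin and phosphoinositide kinase signalling, on which PTPN1 is also known to act, had a median of 0.04 over 24 members (adjusted p = 0.504). The wider family of tyrosine phosphatases had a median of -0.04 over 27 members (adjusted p = 0.51).

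Of the tests that follow, those on markers of other cell types, on a single array for neighbouring genes and on a floor under dim genes were chosen after the result was seen, each in place of an earlier form.

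Large differences leaned towards more transcript in knockdown, with 79 genes at least 2-fold higher and 17 lower where the groups were apart, and 85 and 32 over all genes. Of the listed markers of T cells, myeloid, stromal and epithelial or erythroid cells, 33 lay below the median signal in the non-silencing arrays. Their highest difference was 0.28 (TRAT1), which argues against RNA from cells that express these markers. The other 31 of the 64 markers were too bright there to show a small share. Stromal cells without the listed markers are not covered. A floor under dim genes cannot be told apart, because with both group means at or above the median signal 71.8% were higher (28 against 11, exact 95% interval 55.1% to 85.0%), but with overlapping groups added the interval was 46.0% to 73.5% (32 against 21), and with both means at or above 6 only 10 against 6 genes remained. Nor was the lean shared with neighbouring genes, whose median difference was -0.0056. RNA from follicular dendritic or other cells, to which FDCSP and PRRX1 would point, an effect of the knockdown itself, an off-target effect of the small interfering RNA and a difference between separate cultures were not tested and stay open.

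Neighbouring genes differed together more than shuffled gene orders allow, with medians over windows of 25 genes from -0.29 to 0.35, against -0.19 to 0.20 in 100 shuffled orders, and 5 runs of extreme windows, the longest of 194 genes from ZDHHC17 to LINC02985 (median 0.23) and the deepest of 9 genes from ZNF438 to PARD3 (median -0.36). A difference that follows the array numbers alike in both groups cancels in the comparison, since each group holds an array of each number, and no test of it is given. Of the 3 runs starting at ZDHHC17, RNF212 and DHTKD1, chosen from these same arrays, 3 of 3 stayed beyond random genes without each array. This argues against a single array for those starting at ZDHHC17 and DHTKD1. For RNF212 to WFS1 it is less clear, as its median of 0.23 fell to 0.16 without non-silencing array 2 and to 0.13 without knockdown array 1. Both bootstrap intervals (0.038 to 0.20 and 0.019 to 0.23) overlapped the range of random genes. For the others a single array cannot be told apart. Without non-silencing array 2 ABCF1 to MICA-AS1 fell to 0.055 and ZNF438 to PARD3 to -0.14, and the latter to -0.11 without knockdown array 1, all inside the range of random genes. A candidate explanation is a copy number difference between the knockdown and the non-silencing cells. Of runs sought anew between the arrays numbered 1 alone, 5 were found, none in the stretch from ABCF1 to MICA-AS1. All held between the arrays numbered 2. But neighbouring genes also differed together between the array numbers, correlating at 0.20 there against 0.11 in the knockdown comparison. Neighbours thus varied together between technical replicates too, but that correlation covers all placed genes and not the runs. The runs starting at ZDHHC17 and DHTKD1 hardly differed between the numbers, by medians of 0.014 and 0.0070 for number 2 minus number 1. Those starting at RNF212, ABCF1 and ZNF438 differed by -0.15, -0.085 and 0.23. The runs alone do not show what made neighbours differ. Copy number was not measured here, and a difference in RNA preparation between the groups, whose 18S controls differed by 0.55, also stays open, so this remains a hypothesis.

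For the higher JAK-STAT target list, an overall shift of bright genes is argued against, since the list's median lay at percentile 100 among 10000 matched random lists. Of the 29 members 1 lies inside a run of neighbouring genes, and without it the median was 0.19. Knockdown array 1 is a candidate source of the call, which was lost without that array (adjusted p = 0.292). Between the arrays numbered 2 the median was 0.07, also above 0. The range of random genes there reached 0.079 for sets of 34 genes and 0.093 for sets of 23. That pair of arrays therefore does not set the list's 29 members apart from random genes. A response to the loss of PTPN1 stays open as an untested hypothesis.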
